A study of Homo sapiens with 6 samples.

How the data were processed

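RNA was measured in 6 xenograft tumors of MDA-MB231 cells, 3 labelled shCtrl and 3 labelled shMFNG. Per the labels, 1000000 cells in a basement membrane gel were injected into the mammary fat pad of mice 4 weeks old, tumors were collected after 8 weeks, and 100 ng of total RNA per tumor was labelled for Affymetrix arrays. The authors deposited RMA values from Affymetrix Expression Console, per the labels and the submitters' processing notes; versions are not given in the sources used here. As usually run, RMA corrects the background, sets the probes of all arrays to one distribution and summarises them, so that a change shared by most genes would not show; the steps of this run are not given in the sources used here. That the deposited values are on a log2 scale was read from the values, which run from 1.68 to 15.35 with medians from 7.84 to 8.00. No genome build is given in the sources used here, and detection calls, scan dates and scanner files were not used here, so no batch could be tested. Human probes were used on tumors that hold mouse cells, and how far mouse RNA adds to a probe set is unknown.

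The value table held 33297 probe sets. A table that pairs probe sets with gene symbols listed 21214 of them, 19460 with 1 symbol and 1754 with several; the other 12083 are unnamed here. Symbols were updated through Entrez identifiers in a RefSeq gene table (assembly GRCh38.p14), where 19429 matched and 31 did not and kept their older symbol. Only probe sets with 1 symbol were tested, and for the 769 genes with more than 1 the probe set with the highest mean over all 6 arrays, which left 18417 genes. Among the named genes with several probe sets, those of SMAD2, SDHC, IER3, TAP1, TAP2, HLA-DPB1 and ST6GALNAC2 went the same way, and those of PECAM1 did not (-1.00 and 0.07, the latter at a mean log2 of 4). Of the 60 named genes that passed, 15 had a group mean below the 95th percentile of the odor receptor genes (7.25), 2 of them in both groups, and folds are not given for these. No filter on low values and no further normalization was applied.

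Groups came from the labels. The tumors were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, two-sided), with Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05 as the threshold. The labels do not say that each tumor grew in its own mouse, so the p-values measure the spread between these tumors. An exact permutation test of 3 against 3 values cannot go below 0.1, so single values rest on limma's test alone. The 29 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation called 0 lists, fry called 1 by its directional test (interferon-stimulated genes) and 15 by its mixed test. fry does not compare a list with other genes. Of 700 listed genes 636 were measured, some in more than 1 list.

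The lists, the threshold and the rule for named genes were fixed before the data were examined. The rule names MFNG; PIK3CG, the 4 Notch receptors, HES1, HEY1, CDH1, VIM and CD44 whatever their result; the 15 largest rises and 15 largest falls among genes that pass and whose groups do not overlap; and up to 4 members per list with the smallest p. OASL and TGFBR3 were added after their values were seen. So was CD68, which is named only among the other observations and was not followed through the alternatives.

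The search for runs of neighbouring genes was designed after the data were examined, settings included. Expressed genes (mean log2 of at least 8; 11190 genes) were ordered by their positions in the same RefSeq table, used only for which genes neighbour each other. A running median over 41 genes was compared with the extremes of 200 shuffled orders, which gave a threshold of 0.159, and runs of at least 20 genes were kept, a minimum set after shorter runs were seen. The running median was not computed for the first and last 20 expressed genes of each chromosome, so no run could be found there. Figures were drawn with matplotlib 3.10.9.

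On simulated data for this comparison (18417 genes, 100 changed by 0.5 and 100 by 1.0 on the log2 scale), limma recovered 32% and 97% of them, with 5 unchanged genes among 134 calls. A list shifted by 0.3 was called and 0 of the others were. Genes were drawn independently of each other there, so lists whose members vary together were not covered. In the measured data the estimated correlation within a list reached 0.828 (hypoxia) and was 0.0148 for interferon-stimulated genes. The run search found 0 runs without a shift and 1 with a simulated run of 100 genes shifted by 0.3, of which it covered 87%. Its fold changes were also drawn independently, so false runs from neighbours that vary together were not covered. Most runs found in the measured data were shorter and shifted less than the simulated one. Alternatives covered the normalization, filters on low values, the choice of probe sets, the variance model, array weights, the replicate number as a block, each tumor left out in turn, the thresholds and the list test; 2 more, which concern the runs, were added after the data were examined.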

Results

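Gene expression was measured in 6 tumors grown from MDA-MB231 cells, a human triple-negative breast cancer line, in the mammary fat pad of immunodeficient mice. Per the labels, the injected cells were stable clones that carried a short hairpin RNA against MFNG or a control hairpin. MFNG (manic fringe) is a glycosyltransferase that adds sugars to Notch receptors and changes their response to ligands. The groups held 3 tumors labelled shCtrl (replicates 1, 4 and 5) and 3 tumors labelled shMFNG (replicates 1, 2 and 5), with 1 array per tumor. The median log2 value of an array lay between 7.84 and 8.00, and the number of arrays limits the precision. Each tumor correlated best with a tumor of its own group (Pearson's r across genes from 0.993 to 0.997 within groups and from 0.989 to 0.993 between them, where genes are not independent replicates). The first principal component, with 42.7% of the variance, separated the groups. The titles carry 1 further number per group whose meaning the labels do not give, and if it marks a clone, the hairpin and any other difference between the clones cannot be told apart. The comparison asks which genes differ between tumors grown from the cells with the MFNG hairpin and those grown from the control cells.

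The targeted gene did not pass the test. MFNG was at 7.31, 7.26 and 7.16 in the shCtrl tumors (replicates 1, 4 and 5) and at 7.22, 7.30 and 7.07 in the shMFNG tumors (replicates 1, 2 and 5). The group means were 7.25 ± 0.08 and 7.19 ± 0.12 (log2, SD, n = 3 each), a log2 fold change of -0.05 (95% confidence interval -0.26 to 0.15, limma adjusted p = 0.833). The interval excludes a 2-fold difference in this probe set's signal, which was near the array's background: among 341 genes of odor receptors, which serve smell in the nose, the 95th percentile of the mean was 7.25, and 94.4% of them lay below MFNG. No check of the labels from the targeted gene was had, so the groups are called the tumors labelled shMFNG and shCtrl, and each direction below goes by label. The sign of the MFNG difference turned without shMFNG replicate 5 (0.01).

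PIK3CG, the catalytic subunit of phosphoinositide 3-kinase gamma, fell 2.22-fold in the tumors labelled shMFNG. Its mean was 9.16 ± 0.08 in shCtrl and 8.01 ± 0.09 in shMFNG tumors (log2, SD, n = 3), with a log2 fold change of -1.15 (SE 0.09, limma adjusted p = 0.0005334), and it was lower in 3 of 3 tumors. Among the other genes fixed for naming, none of the 4 Notch receptors passed the test. NOTCH4 came closest, at 9.89 ± 0.16 against 9.41 ± 0.11 (log2 fold change -0.47, limma adjusted p = 0.0519), and NOTCH2 was at 11.92 ± 0.04 against 11.66 ± 0.15 (-0.26, limma adjusted p = 0.208). NOTCH1 and NOTCH3 had log2 fold changes of -0.12 and -0.03. The Notch target genes HES1 and HEY1 were at -0.26 and -0.50, neither past the threshold (limma adjusted p = 0.522 and 0.288). The epithelial cadherin CDH1, the mesenchymal filament protein VIM and the surface receptor CD44 were at 0.14, 0.01 and -0.08, and did not pass either. CDH1 lay among the odor receptor genes (6.21 and 6.35) and VIM near the top of the arrays' range (14.53 and 14.54), so little can be read from these probe sets. Without 1 tumor HES1 ranged from -0.43 to -0.12 and HEY1 from -0.69 to -0.28. NOTCH1 then ranged from -0.19 to -0.04, NOTCH3 from -0.05 to -0.01 and CD44 from -0.16 to -0.02. NOTCH4 passed without shCtrl replicate 5 (limma adjusted p = 0.0256) and under 8 further settings, the most under array weights (0.0123).

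**Figure D1:**
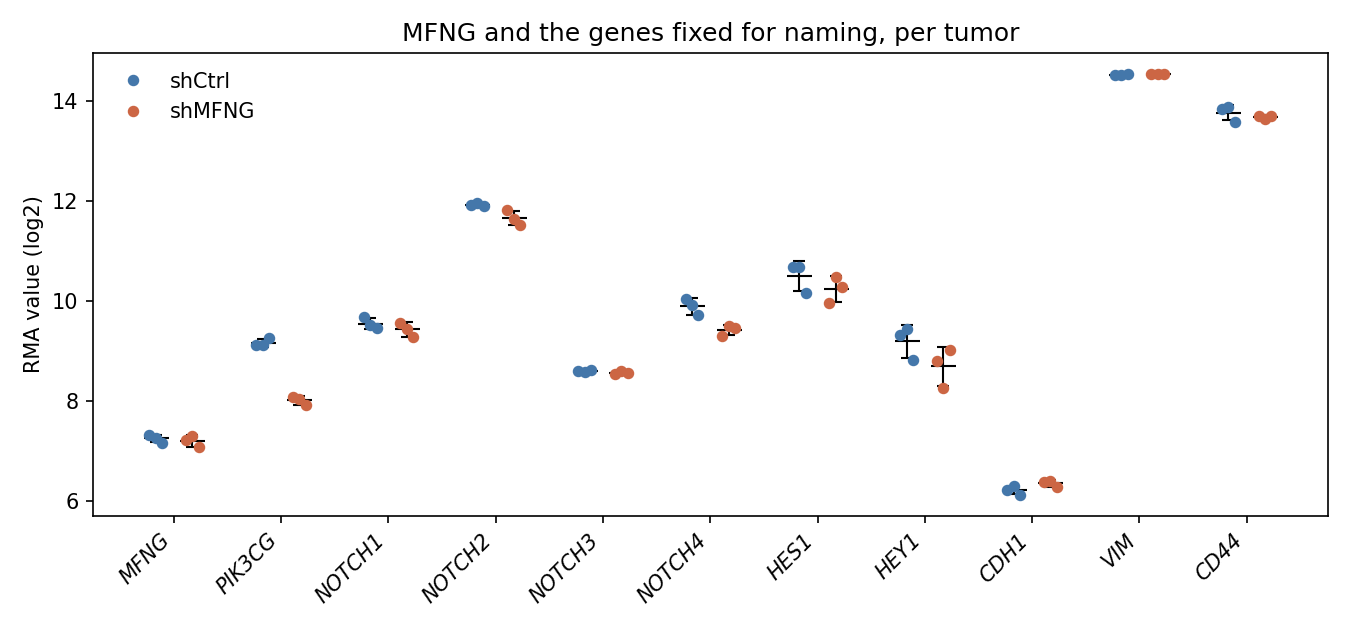
RMA values (log2, vertical axis) of MFNG and the other genes fixed for naming in each of the 3 shCtrl and 3 shMFNG tumors, with the mean and SD of each group as lines. PIK3CG lies at 9.16 against 8.01 without overlap, while the values of MFNG overlap at 7.25 against 7.19.

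Across 18417 genes, 270 rose and 185 fell in the tumors labelled shMFNG. By measured signal the largest rise was that of TMPRSS15 (enteropeptidase), from 5.88 ± 0.42 to 8.35 ± 0.12. LRRN1, a leucine-rich repeat membrane protein, rose 3.95-fold and SPNS2, an exporter of sphingosine-1-phosphate, 3.70-fold. F13A1, the catalytic subunit of coagulation factor XIII, rose 3.24-fold and the cell cycle gene CCND2 (cyclin D2) 3.15-fold. The others of the 15 largest rises were RBM11, SAMSN1, LOC151760, SLAMF7, ADGRL3, POF1B, CXCR4, LINC01711, MCTP2 and MARCHF1. In the shCtrl tumors TMPRSS15, RBM11, SAMSN1, SLAMF7, ADGRL3, POF1B, MCTP2 and MARCHF1 had means below the 95th percentile of the odor receptor genes, and so had RBM11 (4.82 and 6.69) and SAMSN1 (4.495 and 6.148) in both groups, so that no exact fold can be given for these 8. CXCR4, the receptor of the chemokine CXCL12, rose 2.76-fold from 9.59 ± 0.76 to 11.05 ± 0.33, close to the threshold (limma adjusted p = 0.0494).

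By measured signal the largest fall was that of PAEP (glycodelin), 7.26-fold lower, from 11.63 ± 0.94 to 8.77 ± 0.17. The immune receptor CD96 fell 5.57-fold, the vitamin B12 binding protein TCN1 4.48-fold and the protease inhibitor SERPINA1 2.60-fold. GABRA3, a subunit of the GABA-A receptor, fell from 9.61 to 6.95, SGCZ (a sarcoglycan) from 8.81 to 6.27, the protease inhibitor SERPINA3 from 8.76 to 6.73, the membrane receptor HAVCR1 from 8.80 to 6.91 and BCL2A1 from 8.16 to 6.71. For these 5 genes the shMFNG means lay below the 95th percentile of the odor receptor genes, so no exact fold is given. MMP9, a secreted protease that cuts matrix proteins, fell 3.08-fold from 9.97 ± 0.17 to 8.35 ± 0.60. The others of the 15 largest falls, PPP2R2C, ST6GALNAC2, MAMDC2, ITM2C and LAPTM5, lay between 2.64-fold and 2.99-fold.

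These 455 genes passed limma's test at an adjusted p under 0.05, which was 2.47% of those tested. Of them 73 also changed at least 2-fold (38 higher, 35 lower). Of all genes 21.1% had groups that did not overlap, where chance gives 10%. The count moved to 145 without shCtrl replicate 1, 110 without shCtrl replicate 4, 123, 132 and 240 without shMFNG replicates 1, 2 and 5, and 621 without shCtrl replicate 5; 78 genes passed in all 6 of these fits. Of the 15 rises 13 were among these; POF1B lost its call without 3 single tumors and CXCR4 without 5 (limma adjusted p at most 0.174). Of the 15 falls 8 were. SERPINA1 lost its call without shMFNG replicate 1 and GABRA3 without shMFNG replicate 1 or 2, while SERPINA3, MMP9, ST6GALNAC2, MAMDC2 and LAPTM5 lost theirs without 3 or more single tumors (limma adjusted p at most 0.127, for SERPINA3).

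Of 29 gene lists fixed beforehand, 4 were called by camera at the preset correlation, all lower in the tumors labelled shMFNG. With an estimated correlation camera in limma called 0 (1 at an unadjusted p under 0.05), and fry in limma called 1 by its directional test, that of interferon-stimulated genes. At the preset correlation every other split of the tumors into 3 and 3 also called lists, from 3 to 13. A camera call at that preset, kept or not without a tumor, is thus by itself no support for a group difference. Interferon-stimulated genes moved most: 29 of 34 measured members were lower and 5 fell. SAMD9L fell 1.81-fold, IFIT2 2.17-fold, SAMD9 1.96-fold and IFIT3 1.66-fold, and OASL, named after its values were seen, 2.20-fold. IFIT2, IFIT3 and OASL are antiviral proteins made in response to interferon. Adjusted over the list alone, 14 members fell. The list's median log2 fold change was -0.30 (camera in limma, adjusted p = 8.382e-11; adjusted p = 0.0788 with an estimated correlation), and its mean deviation was above 0 in 3 of 3 shCtrl tumors and below 0 in 3 of 3 shMFNG tumors. Among single genes only SAMD9L kept its call without each tumor in turn; IFIT2 and SAMD9 lost it without shMFNG replicate 1 (limma adjusted p = 0.0613 and 0.0611).

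The list for extracellular matrix and invasion had a median log2 fold change of -0.11, with 9 of 37 members falling and none rising, and 9 also fell adjusted over the list alone. Besides MMP9, the basement membrane chain LAMA4 fell from 7.98 to 7.14, the collagen VI chain COL6A1 fell 2.24-fold and the protease inhibitor SERPINE2 1.97-fold. The list was called by camera in limma (adjusted p = 2.953e-05; adjusted p = 0.985 with an estimated correlation). The mean over the list was lower in 3 of 3 shMFNG tumors than in any shCtrl tumor (difference -0.206), and so was that of the macrophage and leukocyte markers (-0.207; exact permutation p = 0.1 for each, the smallest possible). For the matrix list shCtrl replicate 5 lay at a mean deviation of -0.041. That was nearer to the shMFNG tumors (-0.128 to -0.077) than to shCtrl replicates 1 and 4 (0.196 and 0.154). Without shCtrl replicate 1 the median of the extracellular matrix list was -0.04, where camera in limma at the preset correlation still called it (adjusted p = 0.0006117). LAMA4 kept its call without each tumor in turn, while COL6A1 lost it without shMFNG replicate 1 (limma adjusted p = 0.0568) and SERPINE2 without shCtrl replicate 4 or shMFNG replicate 1 or 2 (at most 0.0611).

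The cell cycle list had a median log2 fold change of -0.21, and 30 of 37 members were lower. MCM5, part of the helicase that opens DNA for replication, fell 1.46-fold; the other 36 did not pass, among them MKI67 at -0.40 (limma adjusted p = 0.123), and 1 fell adjusted over the list alone. camera in limma gave an adjusted p of 2.793e-06 (adjusted p = 0.985 with an estimated correlation). The difference lay mostly in shCtrl replicate 5, whose mean deviation over the list was 0.314, against -0.012 and -0.041 in the other shCtrl tumors and -0.053 to -0.137 in the shMFNG tumors. Without that tumor the list's median was -0.08 and its call ended (adjusted p = 0.0761). The same tumor had the lowest mean of the hypoxia list (-0.442, against 0.271 and 0.237 in the other shCtrl tumors and -0.107 to 0.114 in the shMFNG tumors). The MCM5 call ended without shCtrl replicate 1 or 4 or shMFNG replicate 1 or 2 (limma adjusted p at most 0.0713).

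Of 26 measured PI3K-AKT genes, PIK3CG fell and INPP4B, a lipid phosphatase that acts on products of the pathway, rose 2.10-fold; these 2 also passed adjusted over the list alone. The list's median was -0.11, with 19 members lower (camera in limma, adjusted p = 0.0178; adjusted p = 0.985 with an estimated correlation). AKT1, at -0.25, did not pass (limma adjusted p = 0.169). The list's call ended without shCtrl replicate 1 (adjusted p = 0.125), shMFNG replicate 2 (0.126) or shMFNG replicate 5 (0.0583), with only genes above the median mean (0.431) and under fry in limma (0.489), and that of INPP4B without shMFNG replicate 1 (0.0604).

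**Figure D2:**
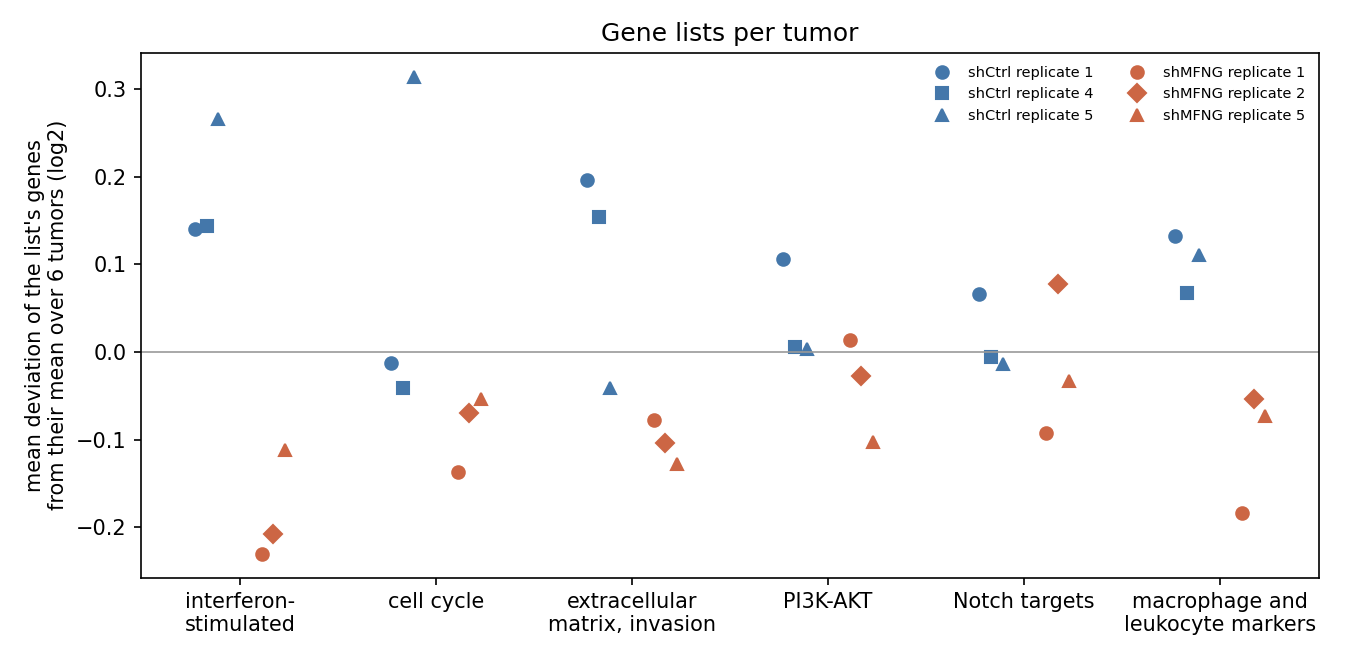
Mean deviation (log2, vertical axis) of the measured members of 6 gene lists from their mean over all 6 tumors, with 1 point per tumor, coloured by group and shaped by replicate number. Interferon-stimulated genes lie above 0 in the 3 shCtrl tumors and below 0 in the 3 shMFNG tumors, while the cell cycle list is set apart by shCtrl replicate 5 at 0.314.

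Of 32 measured Notch pathway components 1 passed: APH1A, a subunit of gamma-secretase, rose 1.37-fold (limma adjusted p = 0.0283). Adjusted over the list alone, NOTCH4 fell as well. Of 19 measured Notch target genes, 0 passed limma's test over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 4, among them CDKN1A at -0.43 and ID3 at 0.24, and for 15.6% of all genes tested. The medians of the lists were -0.01 and 0.04 (camera in limma, adjusted p = 0.985 and 0.72). Of the 6 fits that left out 1 tumor, the APH1A call was kept in the 1 without shCtrl replicate 5 (limma adjusted p from 0.0665 to 0.0949 in the others), and with the running median of neighbouring genes subtracted it ended (0.442).

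Among 23 mesenchymal genes, 4 rose and none fell, also adjusted over the list alone, while the list's median was -0.03 and its mean 0.11 (camera in limma, upward, adjusted p = 0.72). TCF4 rose 2.46-fold, the transcription factor SNAI2 (Slug) 1.82-fold, the smooth muscle protein TAGLN 1.70-fold and the neural cadherin CDH2 1.48-fold. In the list for TGF-beta and BMP signalling (median 0.05, adjusted p = 0.72), the ligands TGFB2 (2.18-fold) and BMP4 (1.67-fold) and the signal transducers SMAD2 (1.74-fold) and SMAD4 (1.53-fold) rose. TGFBR3, named after its values were seen, fell 1.39-fold; adjusted over the list alone, 5 of 26 members rose and 3 fell. TCF4, SNAI2 and SMAD2 kept their calls without each tumor in turn; the others lost theirs without 2 or more single tumors, and TAGLN and TGFBR3 without any of the 6 (limma adjusted p at most 0.105 and 0.134).

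Among 24 epithelial and luminal genes SPDEF rose 1.40-fold, and among 17 stem-like genes DCLK1 rose 1.46-fold while the drug exporter ABCG2 fell from 7.32 to 6.74. In the WNT list the receptors FZD8 and FZD1 rose 1.44-fold and fell 1.39-fold. CA12, a carbonic anhydrase in the hypoxia list, fell 2.16-fold, the cytokine LIF 1.39-fold, the early response gene EGR1 1.41-fold, and the survival gene BCL2A1, in the apoptosis list, fell as given above. Of these, BCL2A1 kept its call without each tumor in turn and CA12 lost it only without shCtrl replicate 4 (limma adjusted p = 0.0507), while the others lost theirs without 4 or more single tumors. None of these lists was called by camera in limma. The medians were 0.02 for epithelial genes (adjusted p = 0.916), -0.02 for stem-like genes (0.469), 0.04 for WNT genes (0.72), 0.005 for hypoxia (0.689), -0.04 for cytokines (0.415), 0.02 for early response genes (0.933) and 0.01 for apoptosis (0.916). Adjusted over the list alone, 3 epithelial, 7 stem-like, 4 WNT, 1 hypoxia, 3 cytokine, 2 early response and 4 apoptosis genes passed. Without shCtrl replicate 5 the hypoxia list was called lower (median -0.18, adjusted p = 4.697e-06), as were antigen presentation (-0.16), glycolysis (-0.08) and endothelial markers (-0.05).

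No member of the lists for basal, glycolysis, cholesterol biosynthesis, unfolded protein response, antigen presentation, heat shock, ribosomal protein or oxidative phosphorylation genes passed limma's test over all genes. With the Notch targets, these 9 lists had 30 of 172 members at an unadjusted p under 0.05, where 15.6% of all genes tested had one. Adjusted over the list alone, 8 passed: 4 heat shock, 3 cholesterol and 1 oxidative phosphorylation genes. Heat shock genes were higher in 10 of 12 members, with DNAJB1 at 0.49 (limma adjusted p = 0.0545). The mean over this list was higher in 3 of 3 shMFNG tumors than in any shCtrl tumor (difference 0.227, exact permutation p = 0.1, the smallest possible). The medians were 0.11 for heat shock (camera in limma, adjusted p = 0.196), -0.12 for antigen presentation (0.0623), -0.06 for glycolysis (0.531), -0.03 for cholesterol biosynthesis (0.36), 0.05 for the unfolded protein response (0.916), 0.04 for basal genes (0.754), 0.02 for ribosomal proteins (0.72) and -0.04 for oxidative phosphorylation (0.385). The signs of the median, the mean and the test differed for the lists of Notch components, Notch targets, epithelial, basal, apoptosis, hypoxia, unfolded protein response, early response, adipocyte and red blood cell genes, besides the mesenchymal list.

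Markers of cell types that the mouse host could contribute were read from probes for human genes. LAPTM5, a lysosomal protein of blood cells, fell 2.64-fold and was the 1 of 20 macrophage and leukocyte markers that passed. That list's median was -0.07 (camera in limma, adjusted p = 0.0931), and its mean was lower in 3 of 3 shMFNG tumors than in any shCtrl tumor, as were those of the interferon-stimulated, extracellular matrix and cell cycle lists. CD14, at -1.06, did not pass (limma adjusted p = 0.0837). Among endothelial markers TIE1 fell 1.73-fold (limma adjusted p = 0.0488), a call that ended without any 1 of the 6 tumors, and the list's median was -0.01 (adjusted p = 0.385). Adjusted over the list alone, 3 leukocyte and 2 endothelial markers passed. No fibroblast, adipocyte, skeletal muscle or red blood cell marker passed limma's test over all genes or over the list alone. Of the 58 measured members of these lists 3 had an unadjusted p under 0.05, against 15.6% of all genes tested. These lists' medians were 0.07, 0.02, 0.05 and -0.004 (camera in limma, adjusted p = 0.537, 0.916, 0.487 and 0.985).

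When expressed genes were set in the order of their positions, fold changes of neighbours ran together. This search was made after the data were examined. Adjacent genes correlated at r = 0.262 across 11190 genes, above the highest of 200 shuffled orders (0.024), and 10 runs of at least 20 genes stood out. Expressed genes between NAP1L5 and WWC2 had a median log2 fold change of 0.34, those between RMC1 and TMX3 0.33, those between DNMT3B and RALGAPB 0.26 and those between ACP6 and EXO1 0.26. Smaller positive medians lay between AIFM1 and EOLA2 (0.19) and between DNMT1 and GADD45GIP1 (0.17). Lower medians lay between DMTF1 and LAMTOR4 (-0.22), VGF and SSBP1 (-0.20), NSUN2 and EMB (-0.20), and DCAF11 and FAM177A1 (-0.16). The runs held 9.97% of the expressed genes and 146 of the 356 expressed genes that passed, 145 of them in their run's direction, counts that follow in large part from choosing the runs by the fold changes of these genes. In the runs that start at DMTF1 and VGF, shCtrl replicate 5 lay at 0.308 and 0.29 relative to the mean of the 6 tumors, and the other shCtrl tumors between -0.002 and 0.031. From AIFM1 that tumor lay at -0.282 while shCtrl replicate 1 (0.03) and shMFNG replicate 1 (0.032) were alike, and from DNMT1 it lay at 0.074, within the shMFNG tumors (0.053 to 0.129).

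Several genes named above lie in such runs: TCF4, CDH2, SMAD2 and SMAD4 between RMC1 and TMX3, PIK3CG between VGF and SSBP1, SAMD9 and SAMD9L between DMTF1 and LAMTOR4 with FZD1, INPP4B and MARCHF1 between NAP1L5 and WWC2, and TGFB2, APH1A and SLAMF7 between ACP6 and EXO1. After the running median of the expressed neighbours was subtracted, PIK3CG (-0.95, limma adjusted p = 0.00144), SAMD9L (-0.59, 0.0217) and TCF4 (0.84, 0.0496) still passed, TCF4 barely. The error of the running median was not counted, so TCF4 is hardly set apart from SMAD2 (limma adjusted p = 0.0738). SMAD2 (0.43), SMAD4 (0.13), INPP4B (0.66), TGFB2 (0.79), SAMD9 (-0.70), APH1A (0.17) and FZD1 (-0.21) did not. CDH2, SLAMF7 and MARCHF1 lay below the level of the expressed genes and were not altered. Chromosome ends could not be searched, and genes below that level did not serve to find runs. A named gene outside the runs may therefore still lie in a shifted segment. With all genes of the runs left out, 204 genes passed, 82 higher and 122 lower.

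**Figure D3:**
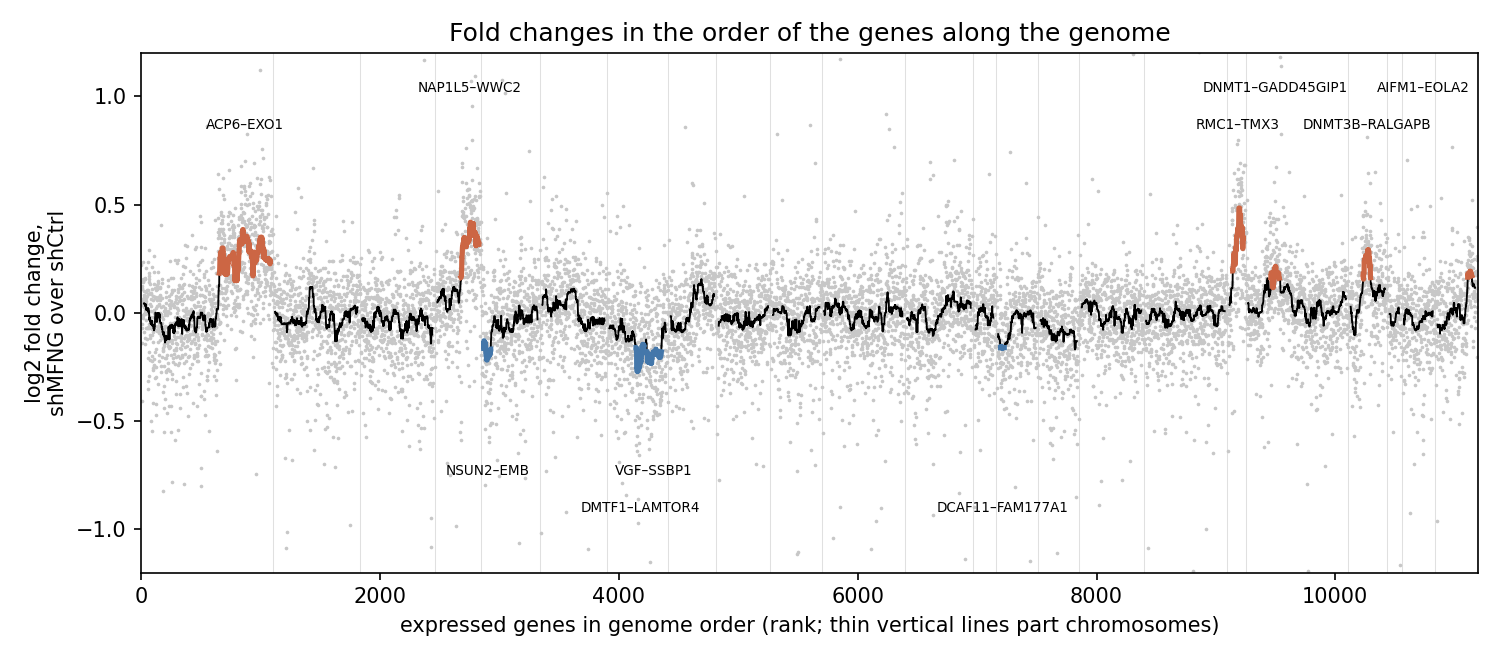
Log2 fold change of shMFNG over shCtrl tumors (vertical axis) for 11190 expressed genes in genome order (horizontal axis, rank), with 1 grey point per gene, the running median of 41 genes as a black line, runs in red (higher) and blue (lower) named by their flanking genes, and 27 genes beyond 1.2 in size not drawn. The medians of the 10 runs reach from -0.22 to 0.34.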

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

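Probe sets that the comparison of genes did not use also differed between the groups. In a limma fit over all 33297 probe sets, an alternative set before the data were examined, 3 of the 1754 that carry several gene symbols passed, all higher in the tumors labelled shMFNG. In the same fit 12 of the 12083 without a listed gene passed, 9 higher and 3 lower. Their genes are not named here, and no explanation was tested.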

How the results depend on the processing

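Leaving out the shifted runs and subtracting the running median of neighbours were chosen after the data were examined. The 455 calls (270 higher, 185 lower) depended on the settings. Of 152 named genes besides MFNG 60 passed, and 19 of them passed in every alternative that tested them. All 60 kept their direction in every alternative run. This was largely fixed beforehand, because the groups of all 455 genes did not overlap. Leaving out 1 tumor, weighting the arrays or changing the variance model could then not turn a sign. With every probe set tested, 57 probe sets passed (35 higher, 22 lower); the prior degrees of freedom then fell from 5.35 to 3.15, and the residual SD of unlisted sets was 0.176. With array weights 1105 passed (630 and 475). Leaving out the runs gave 204 (82 and 122, so that 40.2% were higher instead of 59.3%), with fewer genes tested, and subtracting the running median 191 (93 and 98). A 2-fold minimum gave 73 (38 and 35) and an adjusted p under 0.01 gave 69 (37 and 32), both stricter by construction; an unadjusted p under 0.05 with 1.5-fold gave 320 (165 and 155). Leaving out 1 tumor gave 110 to 621 genes, 59 to 338 higher and 51 to 283 lower, partly from fewer samples. Counts under the other normalizations, filters and variance models lay between 456 and 621, within 1.5 times.

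With the replicate number as a block (replicate block), 444 genes passed, 262 of them among the 455, the PI3K-AKT list was not called (adjusted p = 0.219), and heat shock genes (0.0318) and macrophage and leukocyte markers were (median -0.145, adjusted p = 0.00838). The groups share only the numbers 1 and 5, so shCtrl replicate 4 and shMFNG replicate 2 did not add to the group difference in this fit. Deviations of same-numbered tumors correlated at -0.042 and 0.157, so the numbers were not taken to pair the tumors.

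The number of lists called was 4, and 3 to 7 without 1 tumor, 7 after the running median was subtracted, 0 with the correlation estimated and 1 by fry. For the 25 lists not called, the choice to follow their calls and not their medians was made after 59 of 524 medians had changed sign, in 16 lists; 8 of the 25 were called somewhere, macrophage and leukocyte markers and antigen presentation in 6 alternatives each. MFNG ranged from -0.104 to 0.0095 without 1 tumor (reversed without shMFNG replicate 5) and kept its sign otherwise; it was not tested with only genes above the median mean, nor the red blood cell list under 1 setting. Among named genes that did not pass, the sign turned for VIM (-0.005289 with quantile normalization repeated, -0.0064 with the running median subtracted), CASP6 (-0.014), PMVK (-0.014) and LEF1 (-0.0001967), the last 3 after that subtraction, and HBD (0.195 under the block, -0.254 to 0.045 without 1 tumor). For all these the cause was not tested. Signal over background limits MFNG and other genes near the level of odor receptor genes, whose changes an array understates.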

Other observations

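The tests of gene order, of the size of the trend with signal level, of MFNG against odor receptor genes, of swapped tumors, of host leukocytes and of DNA copy number were chosen only after the results they bear on were seen.

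Tumors of one group also differed from each other. Hypoxia genes were lower in shCtrl replicate 5 (mean deviation -0.442) than in the other 5 tumors (-0.107 to 0.271), with glycolysis (-0.175) and unfolded protein response genes (-0.222) also at their lowest there and cell cycle genes at their highest (0.314). ANGPTL4, a secreted protein in the hypoxia list, was at 10.27 in that tumor and at 11.91 and 11.996 in the other shCtrl tumors; the heat shock gene HSPA6 was at 7.88 against 9.85 and 9.88. Single genes went either way in that tumor: SERPINA3 was at 7.54 in that tumor and at 9.34 and 9.40 in the others, the integrin ITGB3 at 10.95 against 12.24 and 12.21, and GABRA3 at 10.95 against 8.86 and 9.02.

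The 6 tumors can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With limma the real split called 455 genes and the highest other 0, so 1 of the 10 reached the real count; at an unadjusted p under 0.05 the counts were 2877 and at most 1363. For gene lists the real split called 4 and the highest other 13, and 8 of the 10, the real one included, called 4 or more. The split with 13 set shCtrl replicates 1 and 4 with shMFNG replicate 1 against the rest, which points to a structure of the samples that crosses the groups or to members of a list that vary together. With an estimated correlation camera in limma called 0 lists in this split and in each of the others (at most 3 at an unadjusted p under 0.05), and these were not told apart.

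The first pattern is that neighbouring genes shifted together, in 10 runs, and a chance order of the genes is argued against by the correlation of adjacent genes, 0.262 against at most 0.024 in shuffled orders. A trend with signal level is argued against by its size, from -0.0278 to 0.0627 over all genes, and by the correlation of adjacent genes after its removal, 0.26 against at most 0.0264 in shuffled orders; the runs' own shift was then 0.247, over genes that had served to find them. A difference in DNA copy number between the injected cell populations may account for runs in which the tumors of each group lay together, and it stays open. In the runs from DMTF1, VGF, DNMT1 and AIFM1, shCtrl replicate 5 (0.308, 0.29, 0.074 and -0.282) lay apart from the other shCtrl tumors (-0.196 to 0.031). A fixed difference between the injected populations would not by itself give that, and its source was not tested. The test below took all 10 runs together. Genes of intermediate signal (mean log2 from 6 to 8), not used to find the runs, shifted in their direction by 0.0369 relative to such genes outside. Of these genes 62.2% went in the run's direction. Expressed genes, which had served to find the runs, shifted by 0.245. The bootstrap interval (0.0239 to 0.0572) lay above 0 and below the shift that the test required in support. It resampled single genes, which share 10 runs and 6 tumors, so it does not measure the spread between runs or tumors. Much of this signal range lies below the 95th percentile of the odor receptor genes (7.25), where an array understates changes, so the test cannot decide. No DNA was measured, any mechanism that acts on whole segments would look alike, and the hairpin was not separated from the clones.

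The second pattern is the like level of MFNG in both groups. A swap of tumors between the groups is argued against: 0 of the 6 tumors had its most similar tumor in the other group, although labels exchanged between whole groups would pass this test. A signal near that of genes the cells do not express could hide a knockdown, and it cannot be told apart from an unchanged level: the MFNG mean lay above 94.4% of 341 odor receptor genes, between the bounds set for the test, which were chosen after this level was seen. Whether MFNG RNA was lower in the tumors stays open.

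The third pattern is the lower level of interferon-stimulated genes in the tumors labelled shMFNG. Of 34 measured members only 4 lay inside the shifted runs, so leaving these out could hardly change the median. The 30 members outside had a median of -0.267 against -0.299 for all. So few members inside argue against the runs as the whole source. Fewer host leukocytes may contribute: 12 markers above the level of odor receptor genes had a median of -0.109, with 3 higher and 9 lower, which does not decide it. CD68 (12.83 in shCtrl and 12.65 in shMFNG tumors) and LAPTM5 (12.59 and 11.19) had the highest signals of them, which do not rank abundance across probe sets, PTPRC was among the odor receptor genes (5.38 and 5.70), and how many markers the cancer cells themselves express was not tested. The hairpin and the clones stay open as untested sources. camera's call ended with an estimated correlation (adjusted p = 0.0788, and from 2.008e-12 to 1.246e-07 in its other alternatives). That estimate was 0.0148 for this list, near the preset 0.01, so members that vary together explain little of the lost call. fry in limma, which tests against no change, called the list (adjusted p = 0.0174).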
